A study of Mus musculus with 2 samples.

How the data were processed

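H3K9me2, the dimethyl mark on lysine 9 of histone H3, was profiled by chromatin immunoprecipitation and sequencing in cortex of C57BL/6 mouse embryos at embryonic day 15.5. The series holds 1 wild-type library and 1 TBC1D3 transgenic library, and the genotype label put each library in its group. There was therefore no replicate of either genotype. No p-value was computed between genotypes, and every interval below covers counting error alone.

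Each library came with 1 peak list. Per the file headers, the authors called peaks separately in each library against that library's own input with MACS version 2.1.0.20150420, from BAM files whose names carry uni and dedup. The submitters' processing notes also name BWA, with no version, and the build mm10. Per the file headers, both calls used a p cutoff of 0.001, no shift model, summit calling, broad calling off and an effective genome size of 2730871774 bp. The fragment extension was 57 bp for the wild-type library and 111 bp for the transgenic library, per the file headers. The deposited pileup signal is the number of extended fragments over the summit, after the larger of the ChIP and the input had been scaled to the smaller, per the file headers. The deposited fold enrichment is the ratio of that pileup plus 1 to the local background plus 1. The deposited −log10 p and −log10 q are the peak caller's own values. The headers state that q was not calculated, yet the lists hold values for it, and these were used as listed. Fold, p and q are the authors' values per peak and served to describe, rank or filter peaks within a list.

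The depth after filtering was 26735120 ChIP tags and 25431051 input tags for the wild-type library, and 20697113 ChIP tags and 20968853 input tags for the transgenic library, per the file headers. In the wild-type list the ChIP pileup had been multiplied by 0.951, and in the transgenic list by 1. Dividing by these factors gave whole fragments within 0.02 for 100% of the peaks in both lists. The deposited p-values were recomputed as a Poisson tail on the pileup cut to a whole number, with the background taken from the pileup and the fold. All 743 wild-type and all 6253 transgenic values came out within 0.01 on the −log10 scale.

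Peaks were placed on genes with a RefSeq gene table of GRCm38.p6, the assembly that mm10 represents. It gives each gene's start and end without strand or exons, so promoters, exons, introns and untranslated regions were not separated. Of its genes on chromosomes 1 to 19 and X, 340 with a start under 3 Mb, where the assembled chromosomes hold no known bases, were left out as taken to lie on scaffolds, and 49210 genes, 21519 of them protein-coding, were used. A gene was counted as having a peak when a peak overlapped its body extended by 2 kb on both sides. Each peak's midpoint was classed as coding gene body, other gene body, gene flank within 2 kb, or intergenic. No genome sequence was used, so repeat content and base composition, planned at the start, were not analysed here.

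Overlap of the lists (at least 1 bp) and the shares of features were set beside 1000 random placements that kept each peak's width and chromosome. The placements ignore mappability. Gene lists were set beside 10000 random lists of the same size, matched on gene length in 20 bins and on coding status, and a list's place among them is given as a percentile. Lists outside the central 95% of random lists, from the 2.5th percentile up, are called outside the random range, and 25 lists give 1.25 such calls per library by chance. The shares have exact (Clopper-Pearson) 95% binomial intervals and the densities have exact Poisson 95% intervals. Windows of 1 Mb were used for density. To learn how the settings alone act, reads spread evenly over the genome were called with a rebuilt version of the caller's rules in 3 simulated genomes per setting.

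The gene lists, the groups, the overlap rule and the rule for named genes were fixed before the data were examined. The comparison of density with gene number, the correlation of windows, the random spans beside the protocadherin region and the length-matched count of shared genes were added afterwards. Promoters, exons and introns had been part of the fixed design and were replaced by gene bodies and flanks. Named genes were, per library, the 10 coding genes holding the peaks with the lowest q (ties broken by p), the 10 coding genes with most peaks in one list and none in the other, genes of shared peaks, up to 4 members of each list outside the random range, and Ehmt1, Ehmt2, Pax6, Sox2, Eomes, Hopx and Trp53. Other members of lists, genes of the densest windows and genes near a single peak were named after their values were seen. One gene that the rule selected is not reported here. Alternatives were a fold of at least 5, merging within 1 kb, other flanks, overlaps and windows, and the transgenic list cut to the length of the wild-type list. Others, chosen after seeing the data, were a −log10 p of at least 5, finer length bins, matching on gene density, another overlap distance and another rounding of the pileup.

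The steps were tested on simulated data. On lists simulated for the overlap of wild-type and transgenic peaks, 100 of 100 planted overlaps were found. The rebuilt caller recovered 195 of 199 sites planted with wild-type settings. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.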

Results

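H3K9me2 is a repressive histone mark deposited in large part by G9a (Ehmt2) and its partner GLP (Ehmt1). The series title pairs G9a with TBC1D3, a hominoid gene carried here as a transgene in mice, and with cortical progenitors. The comparison was therefore of where H3K9me2 peaks lay in embryonic cortex with and without the transgene, at embryonic day 15.5. The data were 1 peak list per genotype, from 26735120 ChIP tags in the wild type and 20697113 in the transgenic. With 1 library each, the lists describe these libraries and the differences have no replicate check.

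The wild-type list held 743 peaks and the transgenic list 6253, a ratio of 8.42. Peaks were small in both. The median width was 57 bp in the wild type and 115 bp in the transgenic, which lie at or near the fragment extension used in each call. The median peak rested on 6 fragments in each library, and the smallest on 5. The median fold enrichment was 3.90 (range 3.19 to 6.48) among wild-type peaks and 3.62 (range 2.53 to 6.52) among transgenic peaks. The lowest q listed was 0.136 in the wild type and 0.0673 in the transgenic, so 0 peaks of either list had a q of 0.05 or less. A q of 0.1 or less was listed for 0 wild-type and 1447 transgenic peaks, and 95.3% of wild-type peaks carried a q of 1. At a fold of at least 5 the lists shortened to 62 and 166 peaks, and their ratio to 2.68. The genome-wide background was 0.531 fragments in the wild-type call and 0.841 in the transgenic call. A fold of 5 thus asks for more fragments in the transgenic list, and the cut is not alike in both. At a −log10 p of at least 5 the lists held 185 and 2036 peaks, and the ratio rose to 11.

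In the wild-type library the coding genes with the lowest q included Cpne4, Lhcgr, Grin2b, Agbl1, Vsnl1, Adamts12, Wdfy4, Foxp2 and Rasgrp3. Cpne4, a copine that binds membranes in response to calcium, held a peak at chromosome 9, 104858467 to 104858540 (GRCm38, fold 5.94, q 0.321). Lhcgr, the luteinizing hormone receptor, held a peak of fold 5.86 (q 0.324). Grin2b, an NMDA receptor subunit, held 1 peak of fold 5.26 (q 0.643). The peaks of Agbl1, Vsnl1 (a neuronal calcium sensor), Adamts12 (a secreted metalloprotease), Wdfy4, Foxp2 (a forkhead transcription factor) and Rasgrp3 (a Ras activator) had folds from 5.10 in Rasgrp3 to 5.50 in Agbl1. Of these 9 genes, 6 also held transgenic peaks, among them Agbl1 with 6, Cpne4 with 4 and Vsnl1 with 3. Grin2b, Wdfy4 and Rasgrp3 held 0. The mean transgenic density of their chromosomes gives from 0.196 peaks in Lhcgr to 2.02 in Agbl1 over the 9 genes. Several would thus hold a transgenic peak at that density alone. All 9 wild-type peaks lay inside the gene body.

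In the transgenic library the lowest q was 0.0673, and more genes shared it than are named here, Ano2 and Gpc5 among them. By p within that tie the first 10 coding genes were Adamtsl1, Caln1, Spock1, Sgcd, Lingo2, Cald1, Xkr6, Hnmt, Gm29825 and Actn2. Adamtsl1 held the first of these peaks at chromosome 4, 86163369 to 86163526 (fold 5.90). Caln1, a neuronal calcium-binding protein, had its peak at chromosome 5, 130496401 to 130496535 (fold 6.01). Spock1 encodes a brain proteoglycan and its peak had a fold of 5.62. Sgcd (delta-sarcoglycan) and Lingo2 each had a peak of fold 5.97. Hnmt, which inactivates histamine, had its peak in the flank (fold 5.54) and the other 9 had it inside the gene. Wild-type peaks were listed in 2 of the 10, Adamtsl1 and Sgcd, with 1 peak each.

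The coding genes with most transgenic peaks and 0 wild-type peaks were Ano2, Gpc5, Csmd1, Slc24a3, Trpm3, Lsamp, Ntm, Chrm3, Anks1b and Rarb. The wild-type density of their chromosomes gives from 0.0773 peaks in Ano2 to 0.626 in Csmd1, so 0 wild-type peaks in a gene does not set it apart. Ano2, a calcium-activated chloride channel at chromosome 6, 125690419 to 126040133, held 9 peaks (95% interval 4.12 to 17.1), where the mean density of its chromosome gives 0.90. Slc24a3, a sodium/calcium exchanger, held 8 against 1.15. Gpc5 (a glypican) held 8 against 3.84 and Csmd1 8 against 4.54. Trpm3, a cation channel, held 7 against 2.12, and Lsamp, a neuronal adhesion protein, 7 against 6.07. Ntm, Chrm3 (a muscarinic receptor), Anks1b and Rarb (a retinoic acid receptor) held 6 each. In Ano2, Slc24a3, Trpm3, Chrm3 and Rarb the whole interval lay above the chromosome's mean, and in Gpc5, Csmd1, Lsamp, Ntm and Anks1b it did not. These genes were picked as the highest of 21519, which the intervals do not allow for. In the reverse direction Gpr39, a zinc-sensing receptor, held 2 wild-type peaks and 0 transgenic peaks. The other 9 genes of that set held 1 each: Grin2b, Wdfy4, Ms4a15, Rasgrp3, 1700012B07Rik, Mthfd2l, Nxph1, Spata48 and Dusp10. Against the transgenic density, 0 peaks in Gpr39 compares with 0.540 at the mean density of chromosome 1.

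Few genes of cortical progenitors carried a peak in either library. Over all coding genes the share with a peak was 0.911% in the wild type and 5.68% in the transgenic. Of 19 radial glia and apical progenitor genes, which include Pax6, Sox2, Hes1 and Emx2, 0 held a peak in the wild type and 0 in the transgenic. The counts were 0 and 0 among 12 intermediate progenitor genes such as Eomes, and 0 and 0 among 20 cell cycle genes such as Trp53. They were also 0 and 0 among the 25 genes of H3K9 methylation, Ehmt1 and Ehmt2 included. Among 12 basal radial glia genes Palld held a peak in both libraries, Ptprz1 in the transgenic alone, and Hopx in neither. These counts of 1 and 2 lay above their random means of 0.234 and 1.41, at percentiles 88.3 and 71.7. For each of these lists the count was within the random range, so a lack of peaks was not detectable at these list lengths. Length-matched random lists held on average 0.158 wild-type and 0.925 transgenic hits for the radial glia list, 0.124 and 0.631 for the intermediate progenitor list, 0.148 and 0.919 for the cell cycle list, and 0.208 and 1.55 for the methylation list.

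Of 26 axon guidance and synapse genes, 6 held a wild-type peak (Nrxn3, Dscam, Dcc, Sema6d, Cntn4 and Grm7) and 18 a transgenic peak, the same 6 among them. The transgenic count lay at the 98.4th percentile of random lists, whose mean was 12.5, and the wild-type count at the 96.7th. With 100 length bins the transgenic percentile was 21.4 and the wild-type one 62.2, so the excess was not kept once gene length was matched more closely. The named members by q were Csmd1, Grm7 (a metabotropic glutamate receptor, 4 transgenic peaks), Dlg2 (a synaptic scaffold, 5) and Robo2 (a Slit receptor, 3). The mean transgenic density of their chromosomes gives 2.36 in Grm7, 4.43 in Dlg2 and 4.30 in Robo2. Dlg2 was thus near that mean and Robo2 below it. Of 18 cortical neuron genes, such as Tbr1, Bcl11b and Cux1, 0 held a peak in either library. Random lists averaged 3.55 transgenic hits, which put the list at the 0.470th percentile. In the wild type, where random lists averaged 0.753 hits, 0 hits could give no lower percentile than 22.5, so a low count was not detectable. Among 16 interneuron genes 0 held a wild-type peak and Calb2 held a transgenic one. Of 78 voltage-gated and glutamate channel genes 6 held a wild-type peak, Grin2a and Cacna1d among them, and 22 a transgenic peak, at the 87.4th and 86.7th percentiles.

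Of 13 microglia and blood genes, Ptprc and P2ry12 held 1 transgenic peak each and 0 held a wild-type peak. The transgenic percentile was 97.6 with a random mean of 0.366, and it was 44.3 at a −log10 p of at least 5. Glial genes held 0 of 11 in both libraries. Among 13 endothelial, mural and meningeal genes, Cdh5 held a peak in both and Col1a2 in the transgenic alone.

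**Figure D1:**
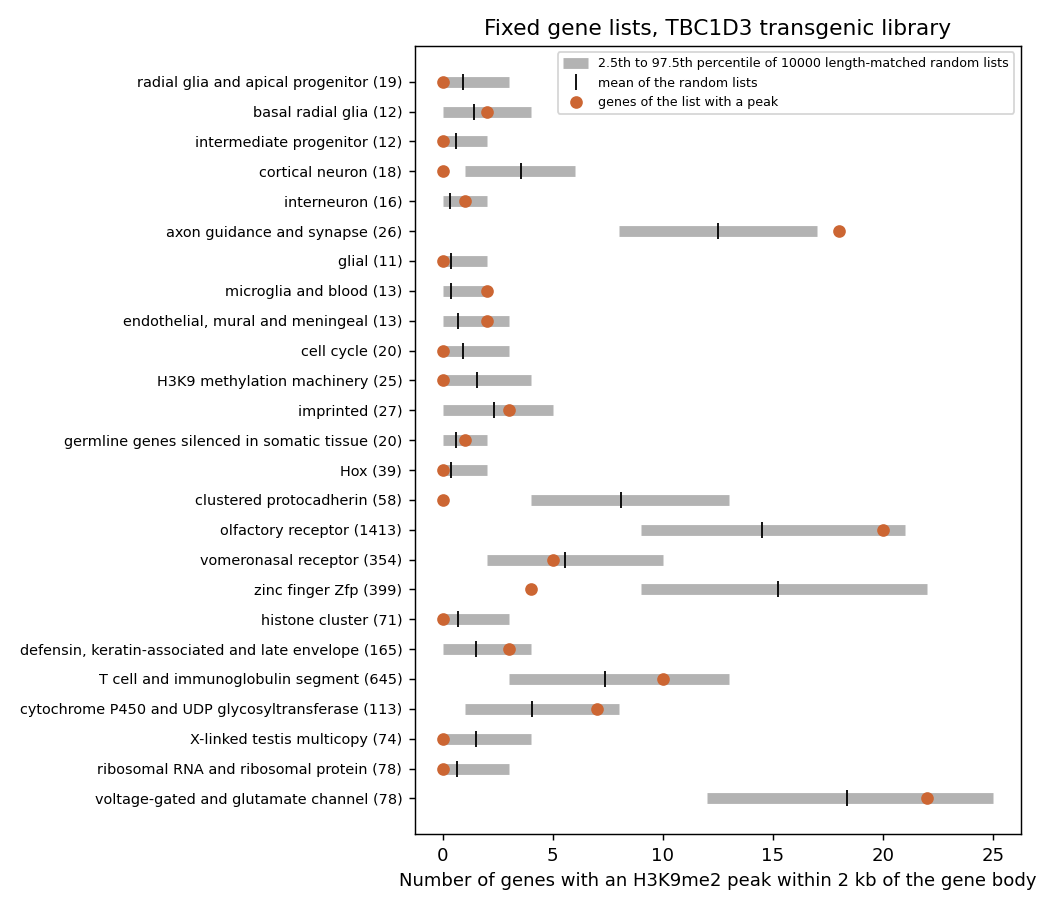
Number of genes in each of 25 fixed lists (list size in brackets) with a transgenic H3K9me2 peak within 2 kb of the gene body. Points are the observed numbers, grey bars the central 95% and ticks the mean of 10000 length-matched random lists. The cortical neuron (0) and Zfp (4) lists lie left of their bars, as do the clustered protocadherins (0), which are 1 region, and the axon guidance and synapse list (18) lies right of its bar.

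Of 399 Zfp zinc finger genes 1 (Zfp831) held a wild-type and 4 held a transgenic peak, against random means of 2.20 and 15.2. The 4 were Zfp385b, Zfp277, Zfp800 and Zfp185. No random list of 10000 held as few transgenic hits. The percentile was 0.035 when lists were also matched on the number of coding genes nearby. Random lists draw genes singly, so Zfp genes that lie next to each other are counted as separate members. The 58 clustered protocadherin genes, adhesion proteins encoded in 1 region of chromosome 18, held 0 peaks in both libraries. They count as 1 place rather than 58, so their percentile among random lists is not a measure of depletion. Their region (36928285 to 37843873, genes and flanks) held 0 wild-type peaks and 1 transgenic peak, which lay over 2 kb from each gene of the list. Of 10000 random autosomal spans of that length, 18.3% held no transgenic peak, with a mean of 2.35. The share with at most 1, the number seen, was not computed and can be no smaller. The region was therefore not shown to be unusual.

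Both libraries had peaks outside coding genes more often than random placement, which ignores mappability and read density. Coding gene bodies held 28.3% of wild-type peaks (95% interval 25.1 to 31.7) and 28.6% of transgenic peaks (27.4 to 29.7), where random placement gave 40.9% and 40.4%. Intergenic sequence held 54.5% and 57.1%, against 45.9% and 46.6%. Other gene bodies, mostly of noncoding genes and pseudogenes, held 12.2% and 10.5%, against 8.59% and 8.41%. Gene flanks held 4.98% and 3.85%, against 4.69% and 4.62%.

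Peak density fell in gene-rich regions in both libraries. Autosomal windows of 1 Mb with more than 15 coding genes held 0.182 wild-type peaks per Mb (95% interval 0.142 to 0.228) and 1.44 transgenic peaks per Mb (1.32 to 1.56). Windows with 1 to 5 coding genes held 0.379 (0.341 to 0.421) and 3.23 (3.12 to 3.35). Windows with 0 coding genes held 0.271 and 2.78 peaks per Mb, which is 1.49 times (1.07 to 2.1) and 1.93 times (1.73 to 2.16) the density of windows with more than 15. At a −log10 p of at least 5 the wild-type ratio was 1.79 with an interval that includes 1 (0.949 to 3.42). In simulation, evenly spread ChIP and input reads at 1.1 times the genome mean gave 1.77 times the calls with wild-type settings. With transgenic settings they gave 1.74 times. Read density per window was not measured, so these ratios cannot be told apart from a small difference in read density. The densest transgenic window lay at chromosome 16, 25000001 to 26000000, with 14 peaks beside Tprg, Trp63 and P3h2. Random placement gave a highest window of 9.72 peaks on average and at most 15. The wild-type maximum was 4 peaks, against 3.58 on average at random. It was reached in 4 windows, which held 10 transgenic peaks (chromosome 14, from 29000001, over Cacna2d3), 12 (chromosome 16, from 9000001, over the NMDA receptor gene Grin2a), 2 (chromosome 17, from 15000001) and 5 (chromosome 7, from 76000001, over Agbl1). The mean of autosomal windows was 2.55 transgenic peaks.

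**Figure D2:**
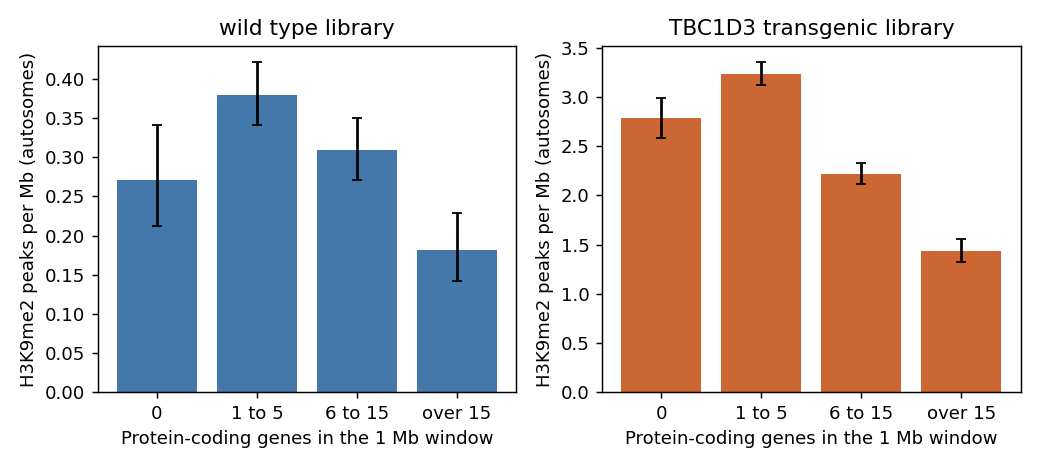
H3K9me2 peaks per Mb in autosomal 1 Mb windows grouped by their number of protein-coding genes, with 1 panel and its own scale per library. Bars are the mean density and error bars the exact Poisson 95% interval. In both libraries density is highest with 1 to 5 genes (0.379 and 3.23 peaks per Mb) and lowest with more than 15 (0.182 and 1.44).

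Chromosome X carried few peaks, most of all in the wild type. The wild-type list held 1 peak on X, at 10792588 to 10792644 and 72.9 kb from the nearest coding gene, Mid1ip1, where the autosomal density gives 51.8. Its ratio of X to autosomal density was 0.0193 (95% interval 0.000488 to 0.108). The transgenic list held 161 peaks on X where the autosomal density gives 425, a ratio of 0.379 (0.322 to 0.443). The intervals of the 2 libraries did not overlap. Wild-type autosomes ranged from 0.218 peaks per Mb on chromosome 6 to 0.426 on chromosome 15, and transgenic autosomes from 2.08 on chromosome 4 to 3.11 on chromosome 13.

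**Figure D3:**
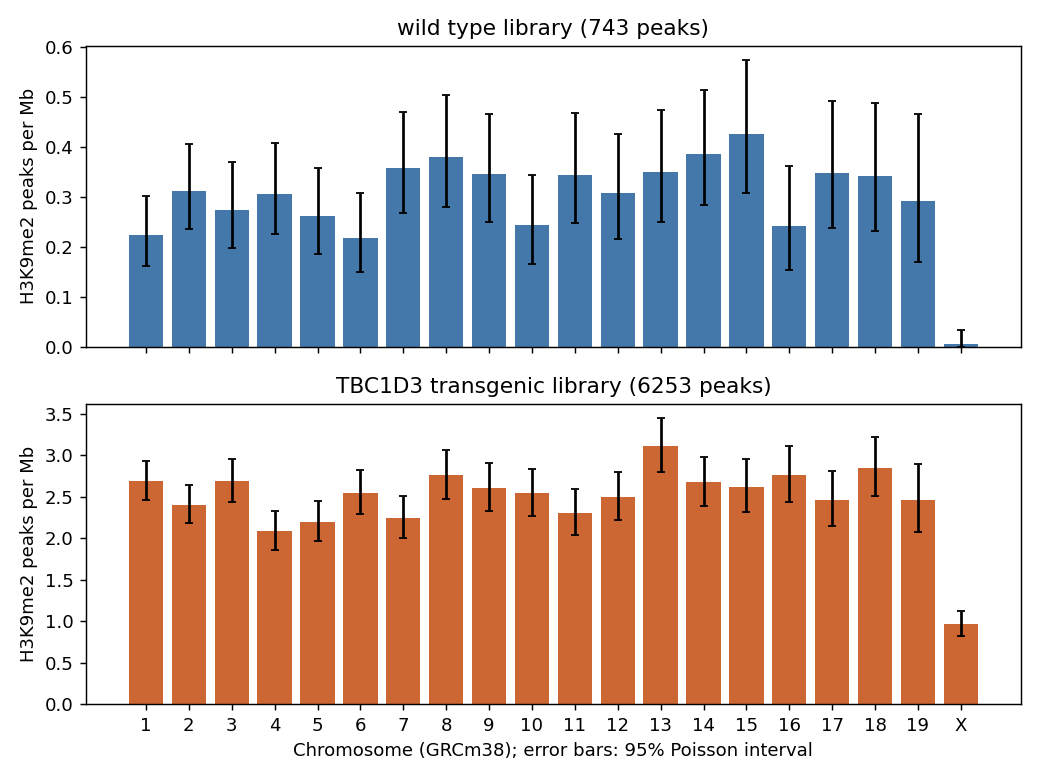
H3K9me2 peaks per Mb on each chromosome, with the wild-type library above and the transgenic library below on its own scale. Bars are the density over the annotated span of the chromosome and error bars the exact Poisson 95% interval. X is the lowest chromosome in both, at 0.00597 peaks per Mb in the wild type and 0.961 in the transgenic.

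The 2 lists shared few positions. Of the 743 wild-type peaks, 4 overlapped a transgenic peak, which is 0.538% (95% interval 0.147 to 1.37). Random placement of the transgenic peaks gave 0.384 on average and at most 3 in 1000 draws. Shifting them by up to 500 kb gave 0.517 on average, and 2 of 1000 draws reached 4. The shared peaks were weak in the wild type, with a q of 1 and folds from 3.34 to 3.42. One lay inside Tmem163, a zinc transporter gene, at chromosome 1, 127643716 to 127643816. The other 3 lay 19.9 kb from Wscd1, 49.2 kb from Nrep and 70.2 kb from Ldb2. Within 1 kb of a transgenic peak lay 22 wild-type peaks, against 4.20 at random and at most 15, or 5.56 after shifts and at most 14. When the transgenic list was cut to its 743 peaks of lowest q, 0 peaks overlapped. At the level of genes, 113 coding genes held a peak in both lists, of 196 with a wild-type and 1223 with a transgenic peak. Independent lists with the same length profile would share 83.4 in 100 length bins, or 66.5 in 20. Across 2375 autosomal 1 Mb windows, which are not independent replicates, the numbers of wild-type and transgenic peaks had a Pearson r of 0.198 and a Spearman rho of 0.194. Within classes of windows with like gene number r ranged from 0.103 to 0.198.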

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

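With 1 library per genotype and peak lists already limited to a p of 0.001, depth and the call's settings limit what the lists can show, and no library could be left out. A −log10 q of at least 5 left 0 peaks and gave no values. Alternatives on promoters were run on gene flanks, and those on base composition were not run, as strand and sequence were not used here. The −log10 p of at least 5, 100 length bins, matching on nearby genes, overlap within 10 kb, the other rounding and all settings of the gene-density ratio were chosen after seeing the data. No paired analysis was possible. The cause of the changes below was not tested, except where a filter shortened a list. A fold of at least 5 left 62 wild-type and 166 transgenic peaks and a ratio of 2.68. A −log10 p of at least 5 left 185 and 2036 and a ratio of 11. Scoring the transgenic peaks with the rounding of the wild-type call left at most 4701 and a ratio of at most 6.33, since widths were not recomputed. Merging within 1 kb kept 742 and 6174. The overlap of 4 became 22 within 1 kb and 75 within 10 kb, 0 with the transgenic list shortened to the wild-type length, and 0 at a −log10 p of at least 5. The 75 stands against 37.2 at random and 49.0 after shifts (at most 75), and the zeros against random means of 0.037 and 0.024, so they carry no information on a lack of overlap. The share of wild-type peaks in coding genes was 22.2% at a −log10 p of at least 5. Flanks of 1 kb and 5 kb held 2.29% and 11.6% of wild-type and 1.82% and 9.0% of transgenic peaks. With a 10 kb extension 1 wild-type list and 5 transgenic lists lay below the 2.5th percentile. The main numbers are 0 and 3, and the 3 include the clustered protocadherins, which, as 1 region, give no measure of depletion. In the wild type 0 hits gave percentiles of 22.5 (cortical neuron) and 10.1 (protocadherin). Those lists could not have been called low there, so 0 against 3 is not a contrast of the libraries. With the shortened transgenic list 0 lay below the 2.5th percentile and 0 above the central 95%, where the main number is 2. The 3 low lists had 0 hits there. That can give no percentile under 24.9 (cortical neuron), 13.5 (protocadherin) and 6.77 (Zfp), so that setting could not have kept them. The same holds for the cortical neuron list at a −log10 p of at least 5 (8.17). Transgenic lists above the central 95% numbered 1 with 100 length bins and 0 when nearby genes were matched. Those below the 2.5th percentile stayed at 3 in both. The axon guidance and synapse percentile moved from 98.4 to 21.4 with 100 length bins. The microglia and blood percentile moved from 97.6 to 44.3 at a −log10 p of at least 5 and to 48.1 with the shortened list. The wild-type ratio of X to autosomal density became 0 at a −log10 p of at least 5. The gene-poor to gene-rich density ratio of the shortened transgenic list was 2.57. For the main results 24 alternatives were classed as moved and 35 as same, though some of the 35 values changed (6253 to 4701 peaks). For the percentiles of the 5 lists outside the random range, 18 alternatives kept the call. The others brought the list into the random range, 9 on the same side of the random median and 3 past it. The microglia and blood values past it are ties at 0 hits.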

Other observations

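The tests of the peak number, of X at lowered read density and of the shifted peaks were chosen after the result was seen. Lists of gene families that cortex does not usually express lay within the random range in both libraries, with genes extended by 2 kb and all peaks used. Of 1413 olfactory receptor genes 1 held a wild-type peak (Olfr1366) and 20 a transgenic peak, against random means of 1.01 and 14.5. At a −log10 p of at least 5 the transgenic olfactory count was 8 against 4.32, at percentile 97.6, just above the random range. Of 354 vomeronasal receptor genes 1 (Vmn2r82) and 5 did, against 0.420 and 5.57. Of 645 T cell receptor and immunoglobulin segments 0 and 10 did, against 1.40 and 7.36, and all 10 belong to the T cell receptor beta locus. Of 113 cytochrome P450 and UDP glycosyltransferase genes 1 (Cyp2d13) and 7 did, against 0.517 and 4.05. Of 165 defensin, keratin-associated and late envelope genes 0 and 3 (Krtap4-9, Krtap19-5 and Lce1j) did, against 0.101 and 1.5. With genes extended by 10 kb, transgenic hits rose above the random range in the olfactory receptor (76, percentile 99.7), defensin, keratin-associated and late envelope (13, percentile 99.3) and cytochrome P450 and UDP glycosyltransferase lists (12, percentile 99.2), and wild-type hits fell below it in the T cell receptor and immunoglobulin list (0 against 3.62, percentile 0.91). Neighbours in these clusters share peaks at that distance, and can share them within 2 kb, so hits at either distance are not independent. The members named here were chosen after their values were seen.

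Imprinted genes held 0 wild-type hits among 27, and transgenic hits in Impact, Snrpn and Kcnq1, against 0.396 and 2.35 at random. Among 20 germline genes 0 held a wild-type peak and Mael held a transgenic one, against 0.628 for the transgenic. Counts were 0 in both libraries for 39 Hox, 71 histone, 78 ribosomal and 74 X-linked testis genes, where the highest random mean was 1.5, for the X-linked list in the transgenic library. With genes extended by 10 kb the histone and X-linked lists, still at 0 transgenic hits, lay at percentiles 2.1 and 1.98. The random lists were not matched on chromosome, and X carried transgenic peaks at 0.379 of the autosomal density, so the X-linked value does not set that list apart from the rest of X.

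The ratio of 8.42 in peak number may come from the read numbers and settings of the peak calls, since reads spread evenly over the genome gave 65.3 wild-type and 851 transgenic calls on average over 3 simulated genomes, a ratio of 13. The wild-type pileup was scaled by 0.951 and truncated to a whole number before the Poisson tail was taken, which scores 5 fragments as 4, and with the rounding exchanged the simulation gave 3224 wild-type and 21 transgenic calls. When the summits alone were scored with the wild-type rounding, with widths left as they were, 4701 of 6253 listed transgenic peaks passed (75.2%, a ratio of 6.33). The same scoring kept 91.6% of simulated calls (a ratio of 11.9), where a full call with that rounding left 21. It therefore cannot show what a full call would leave of the listed peaks. With like rounding in both libraries the simulated transgenic calls were the fewer, 21 against 65.3 or 851 against 3224. In simulation the transgenic excess thus hinged on the difference in rounding. The lists are 11.4 and 7.35 times longer than their simulated counterparts, so both hold more peaks than evenly spread reads gave. A difference by genotype stays open and untested, since 1 library per genotype cannot be told apart from its settings.

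The low number of peaks on X in the wild type may reflect fewer X reads in that library. In simulation with wild-type settings, reads at 0.5 of the genome mean gave calls at 0.0042 of the full-density rate (1 call against 238), under the upper bound of 0.108 for the observed ratio of 0.0193. Densities of 0.6 and 0.7 gave 0.0210 and 0.0840, also under it, so the simulation does not single out 0.5. Evenly spread reads gave 65.3 calls where the wild-type list holds 743, so most listed peaks may respond to read density in another way. Low mappability of X acting alike in both libraries was not settled as the whole cause. The transgenic ratio among peaks of at least 8 fragments was 0.256 (95% interval 0.164 to 0.383), above the wild-type bound of 0.108. That sets part of one list beside the whole of the other. At like fragment numbers the intervals were apart at 6 fragments (0 to 0.209 in the wild type, 0.292 to 0.517 in the transgenic). They overlapped at 5, at 7 and at 8 or more, where the wild type allows a ratio up to 0.528. The sex of the embryos, which the labels used here do not give, is a candidate explanation that was not tested.

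The 22 wild-type peaks within 1 kb of a transgenic peak exceeded what a shared density of megabases gives. Shifting the transgenic peaks by up to 500 kb left 5.56 on average and at most 14 in 1000 draws. Reads piling up at the same positions in ChIP and input could raise the local background there, and the difference from the other 721 wild-type peaks was 0.00667 fragments (0.749 ± 0.184 against 0.742 ± 0.178, SD over peaks). A two-sided permutation test over 100000 draws gave p = 0.859, which leaves this open. Mappability and repeats at these places were not analysed here.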
